A study of Arabidopsis thaliana with 5 samples.

How the data were processed

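The 5 samples of the series were grouped by their labels as air ChIP (1 library), ethylene ChIP (2 libraries, replicates 1 and 2) and 2 inputs, 1 per treatment. Analysis used the peak and summit lists of the 3 ChIP libraries. The run name in the header of the air list carries a replicate label 2, and no other air library was used here. The run names in the headers of all 3 lists carry a protein name other than TREE1, and the protein is named here as in the sample labels. The labels do not say whether the ethylene replicates came from separate batches of seedlings, so the 2 replicates may be technical. Intervals and p-values within a library measure counting error only, not spread between libraries. PCR duplicates are not independent molecules.

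Reads were aligned with BWA to TAIR10, per the submitters' processing notes. Peaks were called by MACS 1.4.2 separately for each ChIP library against the input of the same treatment, per the file headers. Both ethylene lists were called against the same input. Settings per the file headers were a p cutoff of 1e-05, an effective genome size of 1.19e+08, a band width of 300, a tag size of 50 bp, local backgrounds of 1000 and 10000 bp and 1 tag kept per position. The larger data set was scaled to the smaller one, per the file headers. Tags per peak are deposited counts, not normalized. The deposited score of a peak is 10 times the negative log10 of its p-value. Its fold enrichment, a ratio to the local background, and its FDR in percent are also the authors' values, per the file headers. Summit height in the deposited summit list is a signal, the tag pileup at the summit. The header figures gave a duplicate share of 49.7% in air, 53.7% in ethylene library 1 and 48.6% in ethylene library 2, against 19.6% and 16.7% in the air and ethylene inputs. MACS fragment sizes were 79, 71 and 62 bp, per the file headers. The inputs kept 13351505 tags for air and 10918883 for ethylene.

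All else was computed here from the deposited lists, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks on the 5 nuclear chromosomes were used. Regions were connected groups of peaks sharing at least 1 bp. Overlap shares were set against 1000 random placements of the second list within its chromosomes. Shares carry Wilson 95% intervals.

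Gene names and gene positions came from a table of the TAIR10.1 assembly, with 37887 nuclear gene records, of which 27432 were protein-coding. It held neither strand nor sequence, and 12 records with no position were not used. To check its positions against the lists, summits were moved by up to 2000 bp in steps of 100 bp: the share inside coding genes was lowest with no shift in 15 of 15 pairs of library and chromosome. No position from the table is printed, and peak positions are those of the deposited lists. Because strand was missing, the planned window at the gene start was replaced by a window from 1000 bp outside to 200 bp inside either gene end. The planned classes by untranslated region, exon and intron were replaced as well. The classes used were coding gene, 1000 bp outside a coding gene, other gene record, and farther, in that order of priority. The planned test of 16 sequence motifs was not run, as no genome sequence was used here.

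The tests, the 12 gene lists and the rule for named genes were fixed before the data were examined. The rule took the 10 genes bound in all libraries with the smallest sum of fold ranks, the 10 bound in both ethylene libraries with no air peak overlapping the window, and the 10 bound in air with no ethylene peak overlapping it. It added up to 4 bound members of each list, those bound in all libraries first, and all bound members of the ethylene signalling and ethylene response lists. Members bound in air alone, and unbound members of the ethylene lists, are named outside that rule and were chosen after their calls were seen. Of 283 list entries, 282 were matched to the table, and 1 member of the ethylene response list was left out. That member, 1 gene that the naming rule selected and 1 gene family that was tested are not reported here. Each list was tested against all nuclear coding genes with Fisher's exact test, two-sided, adjusted by Benjamini-Hochberg within a library. This test and the matched random lists described below treat genes as independent, although 1 summit can call neighbouring genes. In air 7000 summits in windows gave 9291 bound genes. Some lists hold neighbouring genes, so their p-values may be too small. A list counted as called for ethylene when it passed 0.05 in both ethylene libraries.

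The overlap, gene call and list steps were tested on simulated data. For 13229 simulated sites, the number of regions found in each class equalled the number planted. The class of each single site was not compared. Of the genes given a simulated summit, 200 of 200 were called. The sites lay far apart with no missed or stray peaks, and the summits lay inside the window. These 2 results therefore check the code and say nothing about errors in real lists. Random lists of 20 genes passed an unadjusted p of 0.05 in 3.2% of 1000 draws by Fisher's exact test in the air call, and in 2.5% of 200 draws by matched lists. Their genes were drawn singly, so these rates do not cover lists that hold neighbouring genes. Alternatives covered a score of at least 100, an FDR of at most 1%, lists cut to equal length, overlap of 50% of both peaks, summits within 200 bp, peak midpoints, any overlap with the gene window, other rankings, and each ethylene replicate left out. Wider gene windows, removal of the dense block on chromosome 2, and 10000 random lists matched on gene-free sequence in the window (in 10 bins) were added after seeing the data.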

Results

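Chromatin immunoprecipitation sequencing (ChIP-seq) was used to map where TREE1 tagged with green fluorescent protein sat on the Arabidopsis thaliana genome. The series title places TREE1 beside EIN3, the main transcription factor of ethylene signalling, in gene repression and shoot growth. Shoot tissue came from 3-day-old dark-grown seedlings of a line that expressed the tagged protein from the TREE1 promoter, after 4 h of air or of 10 ppm ethylene, a gaseous plant hormone. There was 1 air library and there were 2 ethylene libraries, each with an anti-GFP antibody. The 2 input libraries, 1 per treatment, entered only through the authors' peak calls. The air library held 18551172 tags, of which 9325092 remained after duplicate removal. Ethylene library 1 was shallower, with 5884897 of 12721634 tags kept, and ethylene library 2 kept 9459860 of 18392702. The deposited lists held 8602 peaks in air, 9156 in ethylene library 1 and 9958 in ethylene library 2, with median widths of 673, 488 and 488 bp. The fold enrichment of a peak is the authors' own value, used here to rank peaks within a list. Median folds were 3.11 in air, 3.99 in ethylene library 1 and 3.39 in ethylene library 2. The lists differed in depth, and air had its own input, so folds of different lists are not on a common scale. The smallest and largest folds were 1.71 and 9.29 in air, 2.33 and 12.7 in ethylene library 1, and 1.69 and 10.6 in ethylene library 2. With a single air library, no difference between air and ethylene had a replicate check.

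The first comparison asked at which regions TREE1-GFP was found in both treatments and at which in only one. Most of the strongest sites were shared. The top-ranked peak of both ethylene lists lay near an end of AT5G64710, on chromosome 5 from 25868933 to 25869429 in ethylene library 1, with fold enrichments of 12.7 and 10.6 in the ethylene libraries and 6.56 in air. WDR5a, which encodes a WD40 protein of histone methyltransferase complexes, had a peak of 7.39-fold in air, 10.4-fold in ethylene library 1 and 9.7-fold in ethylene library 2. One peak on chromosome 1, from 21024215 to 21024986 in air, lay near the ends of the transcription factor genes MYB72 and NF-YC2 and their neighbour AT1G56180, at 8.03-fold in air and 12.04-fold and 7.54-fold in the ethylene libraries. A pair of neighbours on chromosome 2, AT2G33847 and AT2G33850, shared a peak ranked 2 in air, 7 in ethylene library 1 and 11 in ethylene library 2. AT3G57680 and the neighbours AT5G60930 and AT5G60940 completed the 10 genes with the smallest summed fold ranks in the 3 lists.

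Merging the lists wherever peaks shared at least 1 bp gave 13729 regions. Of these, 4850 (35.3%, Wilson 95% interval 34.5 to 36.1%) held a peak in all 3 libraries. Both ethylene libraries, and not air, had a peak in 1545 regions. Fewer regions paired air with 1 ethylene library, namely 987 with ethylene library 1 and 1198 with ethylene library 2. A single library held the remaining regions, 1536 in air, 1535 in ethylene library 1 and 2078 in ethylene library 2. Peaks of the regions found in all libraries had median scores of 99.8 in air, 107 in ethylene library 1 and 114 in ethylene library 2, against 64.7, 64.5 and 67.7 for regions of a single library. The 2 ethylene replicates thus differed from each other at many regions, and both ethylene lists were called against the same input. Restricting the lists to peaks with a score of at least 100 left 793 regions in the ethylene pair class and 762 in air alone. Air with ethylene library 1 then held 340 regions and air with ethylene library 2 held 474. With the lists at equal length the lead of the ethylene pair nearly vanished, at 1214 regions against 1166 and 1090. That cut removed ethylene peaks only, because air was the shortest list.

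**Figure D1:**
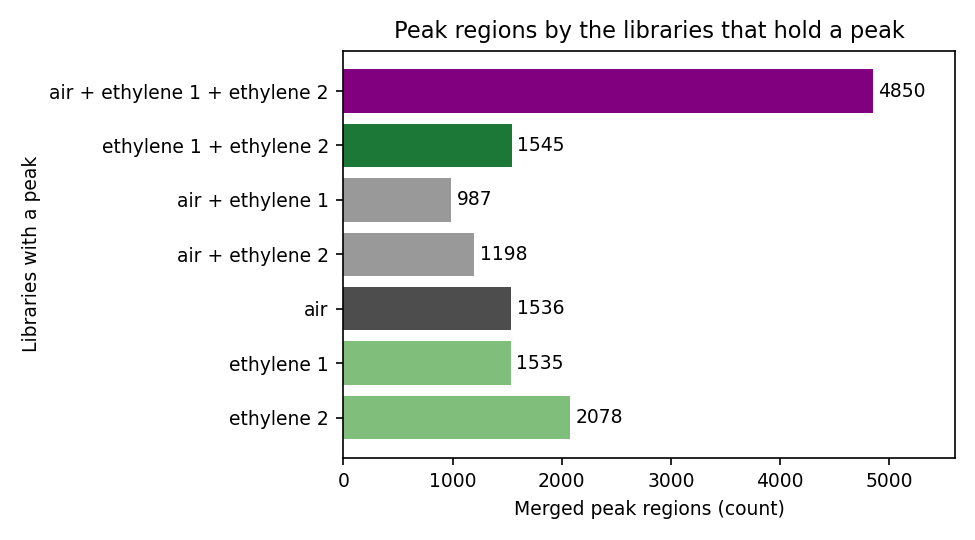
Number of merged peak regions (horizontal axis) for each combination of libraries that held a peak (vertical axis). The 4850 regions of all libraries formed the longest bar, and the 1545 regions of both ethylene libraries exceeded the 987 and 1198 regions that paired air with 1 ethylene library.

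Peaks of one library overlapped those of another for 63.5 to 71.5% of each list. The 2 ethylene libraries overlapped each other at 71.5% of the peaks of library 1 (70.6 to 72.4%) and 65.8% of those of library 2 (64.8 to 66.7%). Air peaks overlapped ethylene library 1 at 68.2% (67.2 to 69.1%) and ethylene library 2 at 70.6% (69.7 to 71.6%). In the other direction, 66.1% of the peaks of ethylene library 1 and 63.5% of those of ethylene library 2 overlapped an air peak. Measured in base pairs, the shared part of the combined peak area was 45.6% for the ethylene pair, 41.9% for air with ethylene library 1 and 42.7% for air with ethylene library 2. Random placement of the second list on its chromosomes gave 7.94 to 10.3%, and placement that kept each peak's distance to a gene end gave 14.2 to 17.2%. All 6 observed shares lay above each of the 1000 random values, with a one-sided permutation p = 0.001, the smallest these placements can give. Among the 500 peaks of highest fold, which include those near AT5G64710, WDR5a and MYB72, 90.4 to 95.4% overlapped a peak of another library, against 62.0 to 70.3% of the remaining peaks.

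**Figure D2:**
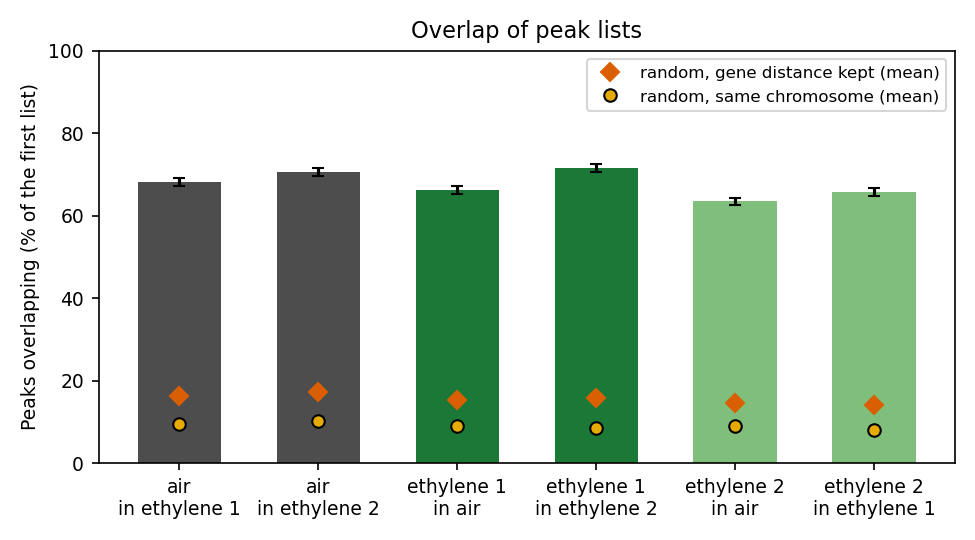
Share of the peaks of one list that overlapped a peak of another list, in percent, for the 6 ordered pairs of libraries; error bars are Wilson 95% intervals. Circles and diamonds mark the mean share under random placement on the same chromosome and with gene distance kept, all at or below 17.2%, while the observed shares ran from 63.5 to 71.5%.

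The second question was where the bound sites lay relative to genes. Summits of all 3 libraries concentrated in the 1000 bp outside protein-coding genes. This zone held 51.2% of the air summits (50.1 to 52.2%), 52.8% in ethylene library 1 (51.8 to 53.8%) and 50.3% in ethylene library 2 (49.3 to 51.3%), against 20.4% at random. Coding gene bodies held fewer summits than random placement gave, with 37.6% in air, 36.6% in ethylene library 1 and 37.3% in ethylene library 2 against 54.2%. Other gene records, which include pseudogenes and noncoding RNAs, counted only where they lay outside coding genes and the 1000 bp around them. That part held 1.395, 1.16 and 1.11% of the summits against 8.59% at random in air. Sequence farther from any coding gene held 9.79, 9.49 and 11.3% against 16.9% at random in air. Each of these shares differed from 1000 random placements with a two-sided permutation p = 0.002, the smallest possible. Random summits were spread evenly along each chromosome, so where reads can be mapped may contribute to these differences. Since the gene table gave no strand, gene starts and gene ends were not separated. The low share of other gene records does not describe noncoding RNA genes as a whole. Of 3480 long noncoding RNA records, 26.5, 27.2 and 28.8% were within 1000 bp of a summit in air, ethylene library 1 and ethylene library 2. The means of 200 random placements were 16.7, 17.6 and 19.1%. Pseudogenes went the other way, as given below.

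A block of chromosome 2 from 3187773 to 3509877 was marked out by its tag density. Within 1 part of the chromosome, it is the smallest stretch holding the peaks above 1 tag per bp of the pooled libraries. The high density of its peaks thus follows in part from how the block was chosen. The peaks inside it held a median of 1.34 tags per bp in air, 1.11 in ethylene library 1 and 1.49 in ethylene library 2, against 0.215, 0.152 and 0.215 for the peaks elsewhere. With 1 tag kept per position and strand, a density of 2 would be the upper limit. Elsewhere in the genome 5, 5 and 3 peaks exceeded 1 tag per bp. Among them was a peak at 2.94 Mb of chromosome 2, with 1.29, 1.55 and 1.35 tags per bp. The block held 17, 31 and 13 peaks, yet it took 4.54% of the tags in peaks in air, 17.1% in ethylene library 1 and 6.07% in ethylene library 2. Tags in all peaks made up 16.4% of the kept tags in air, 16.2% in ethylene library 1 and 13.5% in ethylene library 2, and 15.6, 13.4 and 12.7% without the block. Gene and region counts without the block stayed within a factor of 1.5 of those with it. The block held only 0.20, 0.34 and 0.13% of the peaks of the 3 lists, so its removal could not have moved these counts far.

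**Figure D3:**
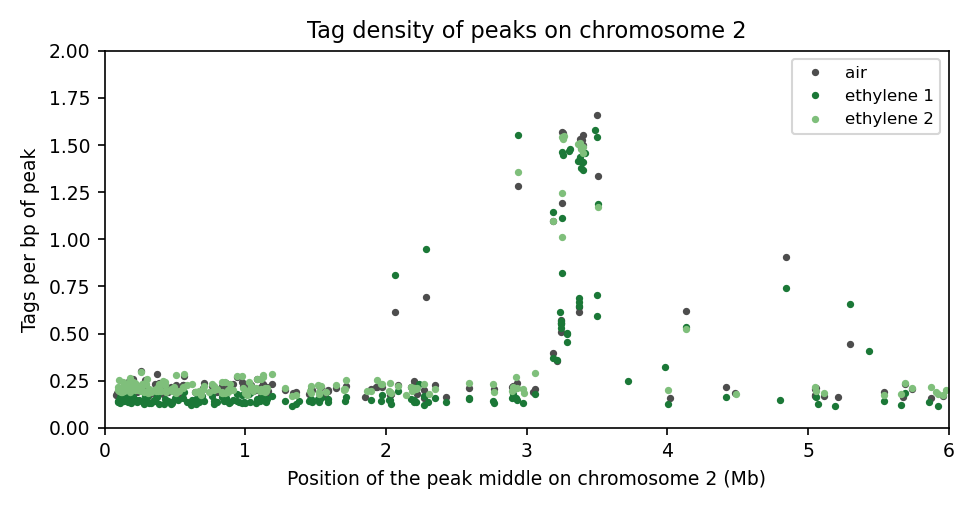
Tags per bp of each peak (vertical axis) against the position of the peak's middle on the first 6 Mb of chromosome 2 (horizontal axis, Mb), with 1 point per peak and library. Peaks of the block from 3187773 to 3509877 reached 1.66 tags per bp in air, while the medians of the peaks elsewhere lay from 0.152 to 0.215.

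The next comparison took the question to genes, with a protein-coding gene called bound when a summit lay from 1000 bp outside to 200 bp inside either of its ends. GRIK1, a kinase that activates the energy sensor SnRK1, led the genes bound in both ethylene libraries with no air peak in the window, at 7.77-fold and 6.8-fold. In the same group were AT2G20470 at 8.53-fold and 5.82-fold, DFR of anthocyanin synthesis at 5.78-fold and 5.6-fold, the transcription factor gene WRKY48 at 6.05-fold and 4.92-fold, and PERK7, a receptor-like kinase gene, at 5.13-fold and 5.07-fold. The neighbours AT3G44400 and AT3G44405, the neighbours LIG6 and SGA2, and AT1G65200 completed those 10. Genes bound in air with no ethylene peak in the window included the prefoldin gene PFD1 and STOMAGEN, which encodes a peptide promoting stomata, each at 4.68-fold. The others were DEG12 with AT3G16555 at 4.65-fold, RPS6 with AT4G31690 at 4.6-fold, AT1G29550 at 4.56-fold, NAC044 with CDC48C at 4.53-fold and AT5G28345 at 4.52-fold.

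Of 27432 nuclear coding genes, 9291 (33.9%) were bound in air, 9948 (36.3%) in ethylene library 1 and 9977 (36.4%) in ethylene library 2. All libraries shared 5804 genes, and 13669 were bound in none. Both ethylene libraries without air bound 1629 genes, against 1123 for air with ethylene library 1 and 1093 for air with ethylene library 2. This order turned with lists of equal length, a cut that removed ethylene peaks only. There the ethylene pair bound 1300 genes, air with ethylene library 1 bound 1353 and air with ethylene library 2 bound 1025. A shared call did not always mean a shared site: 5378 of the 5804 genes, and 1500 of the 1629, had 1 merged region with a summit of each library in the window. Genes bound in 1 library numbered 1271 in air, 1392 in ethylene library 1 and 1451 in ethylene library 2. When any overlap of a peak with the window was taken as presence in the missing library, 1407 genes remained in the ethylene pair class and 1122 in the air class. By summits alone, a score of at least 100 left 936 genes in the ethylene pair class and 839 in the air class, out of 3592, 4292 and 4432 bound genes per library.

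Genes of the ethylene pathway were examined first among 12 gene lists, because the tissue had been exposed to this hormone. Of 20 ethylene response genes, 15 were bound in each ethylene library (75%) and 11 in air (55%). PIF3, ERF2, ERF104, ESE1, PORB and the 4 genes EDF1 to EDF4 were bound in all libraries. CHIB, a basic chitinase gene, EBP and ERF5, which encode ethylene response factors, ARGOS, which promotes organ growth, and PORA, a gene of chlorophyll synthesis, were bound in both ethylene libraries and had no air summit in the window, though an air peak overlapped that of ERF5. ARL was bound in air and ethylene library 2, and ERF6 in air and ethylene library 1. The calls of EBP and ERF6 rested on different regions in their 2 libraries. HLS1, ORE1, RSL4 and PDF1.2 were bound in no library. The list passed Fisher's exact test, two-sided and Benjamini-Hochberg adjusted over the 12 lists, in ethylene library 1 (odds ratio 5.28, adjusted p = 0.00242) and ethylene library 2 (5.25, adjusted p = 0.00185), and it missed the threshold in air (2.39, adjusted p = 0.099). Counting any overlap of a peak with the window, it passed in air too (odds ratio 2.97, adjusted p = 0.03, Fisher's exact test), while a score of at least 100 ended its call in ethylene library 1 (odds ratio 2.91, adjusted p = 0.0683).

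Of 16 ethylene signalling genes, 10 were bound in each ethylene library and 6 in air. CTR1, the kinase that holds the pathway off, the transcription factor genes EIN3 and EIL1, the receptor gene ERS1 and EBF1, an F-box gene that targets EIN3, were bound in all libraries. EBF2, the receptor gene ERS2 and ETP2, an F-box gene that targets EIN2, were bound in both ethylene libraries and had no air summit in the window, but an air peak overlapped the windows of EBF2 and ETP2. The CTR1 peak had folds of 3.33 in air (list median 3.11), 6.49 in ethylene library 1 (3.99) and 4.52 in ethylene library 2 (3.39). EIN2 was bound in air and ethylene library 2, EIN5 and ETP1 in ethylene library 1, and ETR2 in ethylene library 2, while ETR1, EIN4, EIL2 and RTE1 were bound in none. The list did not pass in any library with the main settings (adjusted p = 0.866 in air, 0.0739 and 0.0561 in the ethylene libraries, Fisher's exact test). It passed in ethylene library 2 at a score of at least 100 (odds ratio 5.20, adjusted p = 0.00696) and with equal list lengths (0.0286), and in ethylene library 1 with any overlap (0.0373) and with the whole gene (0.0329, all by Fisher's exact test). Among 14 ethylene biosynthesis genes, 5, 5 and 8 were bound in air, ethylene library 1 and ethylene library 2, and no library passed. ACS8 and ACS6 were among those bound in all. ACS2 was bound in both ethylene libraries with no air summit in the window, a call that ignores any air peak merely overlapping it.

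The list of highly transcribed housekeeping genes had the highest bound share in all 3 libraries, with 21, 22 and 21 of 24 members bound in air, ethylene library 1 and ethylene library 2. Examples bound in all were ACT2, PIP1B, GRP7 and GAPC1, and the adjusted p was 9.94e-07, 2.84e-07 and 3.99e-06. Of 18 circadian clock genes, 15, 16 and 15 were bound, and 12 of them, including LNK2, PRR7, CCA1 and GI, in all libraries (adjusted p = 0.000137, 3.54e-05 and 0.00034, Fisher's exact test). Abscisic acid, cold and drought genes were bound for 14, 13 and 16 of 20 members (adjusted p = 0.00313, 0.0299 and 0.00034, Fisher's exact test), with SNRK2.3, ABI5, NCED3 and CBF2 in all. These 3 lists and ethylene response were the 4 lists that passed in both ethylene libraries. With peaks of a score of at least 100, the housekeeping list alone passed in both, as ethylene response and the circadian clock reached adjusted p = 0.0683 (Fisher's exact test) in ethylene library 1 and abscisic acid reached 0.271 there. Equal list lengths also ended the abscisic acid call in ethylene library 1 (adjusted p = 0.132, Fisher's exact test).

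In air 5 lists passed, namely housekeeping, circadian clock, abscisic acid, auxin and light. Auxin genes were bound for 27 of 43 members in air (adjusted p = 0.000538, Fisher's exact test), 20 in ethylene library 1 (0.222) and 23 in ethylene library 2 (0.0503). In ethylene library 2 the auxin list passed at a score of at least 100 (adjusted p = 0.0315), with equal list lengths (0.0286), any overlap (0.033) and the whole gene (0.00444, all by Fisher's exact test), and against matched random lists (0.0223). AUX1, ARF2, AFB2 and ARF6 were bound in all libraries. The auxin transporter genes PIN2 and PIN7, with GH3.1 and SAUR19, were bound in air alone. Light and photomorphogenesis genes were bound for 20 of 30 members in air (adjusted p = 0.000937, Fisher's exact test), 15 in ethylene library 1 (0.173) and 18 in ethylene library 2 (0.0289), with HY5, FHY1, COP1 and PIF3 in all. Equal list lengths ended the light call in ethylene library 2 (adjusted p = 0.0839), and the whole gene added one in ethylene library 1 (0.0182, both by Fisher's exact test). Gibberellin and brassinosteroid genes (14, 15 and 16 of 28, with BIN2, BRI1, BR6OX2 and PRE1 in all) passed in no library with the main settings. With any overlap they passed in all 3 (adjusted p = 0.0055, 0.022 and 0.00353, Fisher's exact test), and matched random lists gave adjusted p = 0.0348 and 0.0184 in the ethylene libraries (permutation). Corepressor and chromatin genes (11 of 21 in each, with TPL, TPR1, TPR2 and TPR3 in all), cell wall genes (13, 15 and 13 of 29, with CESA1, CESA6, COB and EXPA9 in all) and nuclear photosynthesis genes (11, 12 and 9 of 19, with LHCB4.1, LHCB6, PSBO1 and RBCS2B in all) did not pass with the main settings either. Cell wall genes passed in all 3 libraries with the whole gene (adjusted p = 0.0318, 0.0457 and 0.019), and with any overlap in air (0.0457) and ethylene library 1 (0.0165, all by Fisher's exact test). Photosynthesis genes passed in air at a score of at least 100 (0.0235), with any overlap (0.0158) and with the whole gene (0.0318). In ethylene library 1 they passed with equal list lengths (0.0404), the whole gene (0.0457, all by Fisher's exact test) and matched random lists (0.0348).

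Passing in one library and not in another is not by itself a difference between them. An exact binomial test of the members that changed call was made for each list and each pair of libraries, 36 comparisons in all, and none passed after adjustment (smallest adjusted p = 0.9). Few calls changed, so this says little about most lists: with all changes in 1 direction, 14 of the 36 comparisons could have reached an unadjusted p under 0.05 by the exact test, and 3 could have passed adjustment on their own. The smallest raw value came from auxin, with 8 members bound in air and not in ethylene library 1 and 1 the other way (p = 0.0391, exact binomial test). For ethylene response, 5 members were bound in ethylene library 1 and not in air and 1 the other way (p = 0.219, exact binomial test), and ethylene library 2 gave the same counts. Such a test on the calls of 2 libraries compares those libraries, not the treatments.

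**Figure D4:**
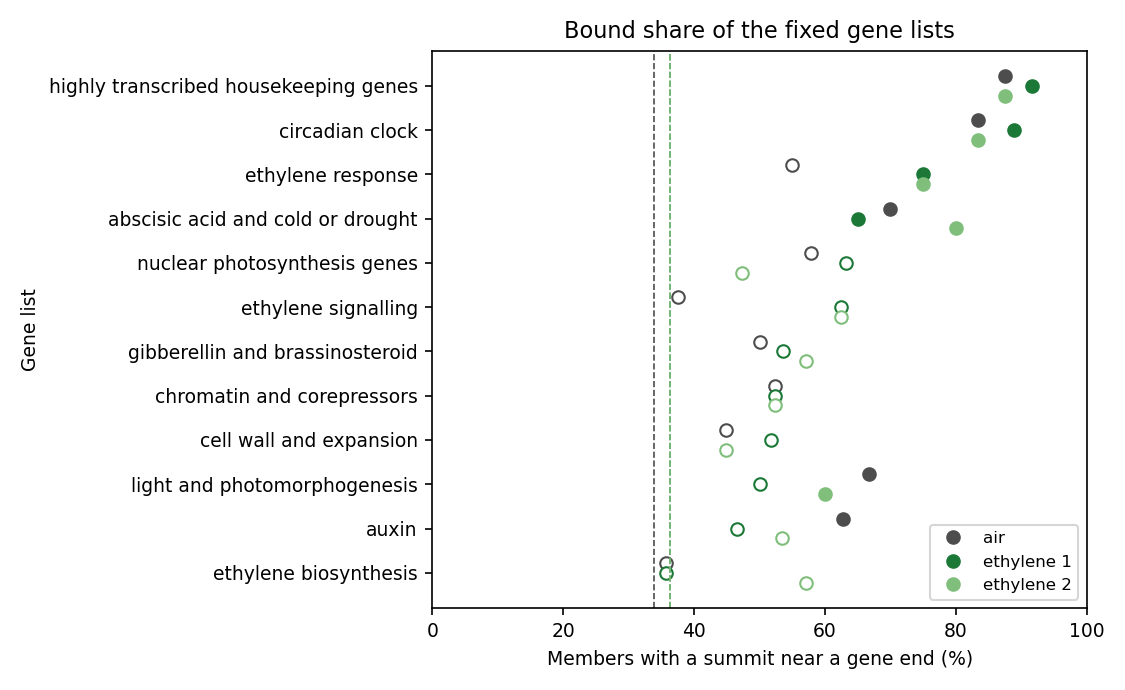
Share of the members of each fixed gene list with a summit near a gene end, in percent (horizontal axis), per library; filled points passed an adjusted p of 0.05 and open points did not, and dashed lines mark the share of all coding genes. Housekeeping genes reached 87.5% or more in every library, and ethylene response genes stood at 75% in both ethylene libraries and 55% in air.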

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

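Lists of equal length were a planned setting, but their use here to test 2 explanations, the matched random lists, the tests of the chromosome 2 block and the values for tRNA and snoRNA genes were chosen after the results had been seen.

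Transfer RNA genes, which the comparisons did not use, lay near summits more often than random placement gave. Of 625 tRNA genes, 54.4% were within 1000 bp of a summit in air, 54.7% in ethylene library 1 and 56.2% in ethylene library 2, and the highest of 200 random placements gave 19.0, 20.2 and 21.0%. The 496 tRNA genes close to a coding gene carried this excess, with shares of 64.9, 65.7 and 67.5%, while the 129 others had 14.0, 12.4 and 12.4%. Of 287 snoRNA genes, 39.7% in air, 49.5% in ethylene library 1 and 50.2% in ethylene library 2 were within 1000 bp of a summit, against random maxima of 23.7, 25.1 and 26.1%. The 41 snoRNA genes away from coding genes had 46.3, 43.9 and 51.2%.

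Regions with a peak in both ethylene libraries and not in air (1545) outnumbered those of air with ethylene library 1 (987) and air with ethylene library 2 (1198). With lists of equal length the lead nearly vanished, at 1214 regions against 1166 and 1090. The ratio to the larger mixed class was 1.04 (exact 95% interval 0.96 to 1.13). Air was the shortest list, so the cut removed ethylene peaks only. It could shrink the ethylene pair class and turn regions of all libraries into mixed ones, so a smaller lead was largely built in. The treatment itself could also lengthen the ethylene lists. This cut therefore cannot decide whether list length is the cause. Peaks near the calling threshold stayed open as an explanation. Where both peaks scored at least 100 and the third library had none, the ethylene pair held 158 regions. Air with ethylene library 1 held 68 there and air with ethylene library 2 held 89 (ratio to the larger 1.78, 1.36 to 2.33). With equal lengths and the top 3038 peaks of each list, the ethylene pair held 91 against 81 and 75 (1.12, 0.824 to 1.53). The input shared by both ethylene lists stayed open, since a low stretch of it could raise both lists at once: the background implied by height over fold was lower in ethylene pair peaks than in mixed peaks of ethylene library 1 (ratio of medians 0.954, bootstrap interval 0.943 to 0.968) and not clearly so in ethylene library 2 (0.995, 0.984 to 1.01). An effect of the ethylene treatment stayed open and untested, as did library depth, because there was 1 air library and the shared ethylene input cannot be told apart from the treatment.

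Housekeeping genes were bound in all 3 libraries for 18 of 24 members. Free sequence around their ends was argued against as a cause: against random lists matched on it, the one-sided permutation p was 0.0001 in each library, the smallest that 10000 draws can give. A signal at highly transcribed genes whatever their function might account for the pattern. Cytosolic ribosomal protein genes served as another such group, with 46 members found by matching gene names, which may be only part of the class. In the ethylene libraries 31 and 26 of them were bound and the group passed. In air 22 were bound (adjusted p = 0.144, Fisher's exact test). Against matched lists the group passed in ethylene library 1 alone (adjusted permutation p = 0.366, 0.0036 and 0.0795 in air and the ethylene libraries). Transcription was not measured here for either group, and this explanation stayed open. The design names no biological explanation for binding shared by all libraries and none was tested, and no ChIP of an untagged line was used here.

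The peaks of the chromosome 2 block took 4.54% of the tags in peaks in air, 17.1% in ethylene library 1 and 6.07% in ethylene library 2. Chromosome 2 of Arabidopsis is known to carry a large insertion of mitochondrial DNA, and reads of the multi-copy mitochondrial genome may map there, which would make the inputs dense too and fold enrichment low. The median fold of the block's peaks was 2.17 in air, 3.52 in ethylene library 1 and 2.14 in ethylene library 2, against 3.11, 3.99 and 3.4 elsewhere, and the ratio reached 0.882 in ethylene library 1 (bootstrap interval 0.808 to 1.04), so this source stayed open. For the peaks above 1 tag per bp alone the ratio was 0.659 in air (0.595 to 0.698), 0.791 in ethylene library 1 (0.756 to 0.822) and 0.629 in ethylene library 2 (0.591 to 0.654). These ratios do not decide the source. At a fixed p cutoff, peaks on a dense background pass at a lower fold whatever their source. Keeping 1 tag per position also limits their fold. Other multi-copy sequence was not excluded, and no biological explanation was tested.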

How the results depend on the processing

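Wider gene windows, removal of the chromosome 2 block and matched random lists were chosen after seeing the data; all other settings were planned. No result past its test changed direction. All 6 overlap shares stayed above random placement in 36 of 36 alternatives, and all 12 location shares stayed on their side of it in 24 of 24. The ethylene pair remained the largest class of 2 libraries with overlap of 50% of both peaks (1831 regions against 983 and 1171) and with summits within 200 bp (1700 against 1099 and 1281), but with equal list lengths its lead nearly vanished (1214 against 1166 and 1090), and for genes the order turned (1300 against 1353 and 1025). The cut to equal length removed ethylene peaks only, so it could lower the ethylene pair class but hardly raise it. An FDR limit of 1% removed no peak, as the largest value was 0.59%, so this limit tests nothing. The FDR limit supplied 6 of the 36 overlap alternatives, and the placement that kept gene distance, already given above, supplied 6 more. The 3 motif alternatives were not run, and the planned windows from the gene start were replaced by windows without strand.

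A score of at least 100 lowered the counts by construction, since 3038, 3560 and 4025 peaks were left. Regions numbered 1456 in all libraries, 793 in the ethylene pair, 340 and 474 in air with ethylene library 1 and 2, and 762, 932 and 1240 in air, ethylene library 1 and ethylene library 2 alone. Bound genes numbered 3592, 4292 and 4432 per library, with 1789 in all, 936 in the ethylene pair, 459 and 505 in the mixed classes and 839 in air alone. Without one or the other ethylene replicate, which merges classes by construction, air alone held 2526 to 2739 regions and 2364 to 2394 genes, and ethylene without air held 3101 to 3637 regions and 3021 to 3080 genes.

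The 4 lists called in both ethylene libraries became 1 at a score of at least 100 and 7 with the whole gene and 1000 bp on either side, and the 5 called in air became 9 with any overlap of peak and window. Equal list lengths ended the abscisic acid call in ethylene library 1 (adjusted p = 0.132, Fisher's exact test) and the light call in ethylene library 2 (0.0839), and left 3 lists called in both; the cause was not tested. Of 679 alternative calls of named genes, 68 differed, 44 of them at a score of at least 100. The FDR limit, which removed no peak, supplied 97 of the 679. Removal of the chromosome 2 block, which took out few peaks, supplied another 97, and none of these differed.

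Ranked by score, the top 500 peaks overlapped at 96% and 97.8% for air in ethylene libraries 1 and 2, 98% and 97% for ethylene library 1 in air and in library 2, and 99% and 99.6% for ethylene library 2 in air and in library 1. The top 1000 by fold gave 86.6% and 87.8% for air in ethylene libraries 1 and 2, 85.9% for ethylene library 1 in air, and 85.7% and 89.7% for ethylene library 2 in air and in library 1, where the cause was not tested.

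No paired analysis was possible because there was only 1 air library.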

Other observations

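The combined test of the ethylene lists, and the choice of the 24 gene families and of noncoding gene classes, were made after the lists had been opened, the families before their values were seen.

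Some gene families outside the fixed lists were bound less often than other coding genes in every library. Cytochrome P450 (CYP) genes were bound for 47, 53 and 55 of 229 members in air, ethylene library 1 and ethylene library 2, or 20.5, 23.1 and 24.0% against 33.9, 36.3 and 36.4% of all coding genes, and the LCR and SCRL genes of small secreted cysteine-rich proteins for 13, 17 and 19 of 107. Mitogen-activated protein kinase (MPK) genes went the other way, with 14, 11 and 14 of 18 members bound (adjusted p = 0.00105, 0.153 and 0.00423, Fisher's exact test over 24 families). Pseudogenes lay within 1000 bp of a summit for 3.57, 3.73 and 3.55% of 3917 records, against means of 26.5, 27.9 and 29.9% under random placement. That placement was even along each chromosome and ignored where reads can be mapped. The low share therefore does not by itself show that TREE1-GFP avoids pseudogenes.

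That families differ beyond the free sequence around gene ends was tested as a hypothesis with matched random lists. Of the 24 families, 3 passed an adjusted p of 0.05 against such lists in all 3 libraries. CYP and LCR with SCRL were among them, so the amount of free sequence does not account for their low shares.

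Ethylene genes may be overrepresented among the calls made in both ethylene libraries and not in air. Of 50 genes in the 3 ethylene lists, 36 were bound in some library, and 10 of these (27.8%) were in that class: EBF2, ERS2, ETP2, CHIB, EBP, ARGOS, ERF5, PORA, ACS2 and ACO3. Other bound genes were in it for 1619 of 13727 (11.8%), an odds ratio of 2.88 (two-sided Fisher's exact p = 0.00736). Genes with an air peak overlapping the window, among them ERF5, EBF2 and ETP2, were then counted as bound but outside the class. This left 6 of the 36 ethylene genes (16.7%) and 1401 of the 13727 others (10.2%) in it. The odds ratio was 1.76 (two-sided Fisher's exact p = 0.261), so the excess depends on how air binding is called. The lists were combined, and ACO3 named, after their calls had been seen, and with 1 air library the test compares these libraries, not the treatments.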
